A study of Homo sapiens with 5 samples.

How the data were processed

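Single-cell RNA sequencing was analysed in 5 libraries from human femoral heads, 2 labelled steroid-induced osteonecrosis (ONFH) and 3 labelled hip osteoarthritis (OA). Per the labels' protocols, tissue was digested with collagenase and dispase, passed over a Percoll gradient, treated with red cell lysis buffer and a red cell antibody, and sorted for live cells with DAPI before droplet capture. Libraries were made with a 10x Genomics 3' kit of version 3, per the labels' protocols. The deposited values were raw UMI counts per gene and barcode made with Cell Ranger 7.0.0, per the file headers, and all were whole numbers. The submitters' processing notes name Cell Ranger 7, STAR 2.7.3, Seurat 5 and the genome build GRCh38, without saying which step each served for these files. Whether intronic reads were counted is not given in the sources used here. Every file held 33538 genes, and the gene positions printed came from GENCODE 29 on GRCh38. Because the samples are human, 102 sex-linked genes were left out of all analyses, which leaves 33436. No annotation of cells was used here.

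The files held 8160 and 2128 barcodes for ONFH replicates 1 and 2 and 8164, 16489 and 11950 for OA replicates 1, 2 and 3, where the labels' protocols state a target of 5000 to 9000 cells. Barcodes with at least 500 UMIs, at least 200 genes and under 20% mitochondrial counts were kept. Doublets were scored with scrublet (expected rate 6%) and removed at a fixed score above 0.2, because the automatic threshold called 1 of 8043 barcodes in ONFH replicate 1. The fixed score removed 159, 27, 259, 838 and 563 barcodes, or 1.98%, 1.30%, 3.22%, 5.10% and 4.93%, in the order above, which does not find doublets of similar cells. In total 44180 of 46891 barcodes were kept. Counts were scaled to the same total per cell and log-transformed, 2000 variable genes were chosen across libraries without immunoglobulin, T cell receptor, mitochondrial and sex-linked genes, and 30 principal components, 15 neighbours and the Leiden method at resolution 1 gave 38 clusters. No correction between libraries was applied.

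Cluster names came from markers of 23 cell classes fixed beforehand. A name needed at least 3 markers enriched in the cluster, a mean log2 enrichment of at least 1, and no lead of another class among the 10 top genes, and 4 clusters stayed unnamed. Of kept cells, 84.3% had the same class when each library was clustered on its own and 86.9% at resolution 2. Shares are percentages of kept cells, with exact Clopper-Pearson 95% intervals and a floor of 3 counts where a class had no cell, both covering counting error alone. Cell numbers per class were tested with edgeR's quasi-likelihood test and with a two-sided exact permutation test of the shares, which with 10 splits cannot go below 0.2.

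Counts were summed per library over all cells and over each class. A class was tested where both groups had at least 2 libraries with 20 or more of its cells, which gave 13 classes. Neutrophils were compared without OA replicate 3 and stromal cells without OA replicate 1. Each fit used edgeR with filterByExpr, TMM scaling and a robust quasi-likelihood test without covariates, with Benjamini-Hochberg adjustment over the genes of that fit at 0.05. Group means and their SDs are CPM on the TMM scale, while levels of single libraries, ratios between classes and the plots use plain totals. Lists of genes, 33 in number, covered steroid and stress responses, energy and lipid metabolism, inflammation, blood and immune cell functions, bone, cartilage, vessels and markers of other cell types. They were tested with limma's camera (correlation 0.01) where at least 5 members were measured, with adjustment over 32 lists for all cells and over 351 tests for the classes. Members of each list were also adjusted over the list alone with edgeR p-values. Each printed list median was also computed with genes that had no counts in a group at their bound (3 counts over the UMIs of that group), which left it as it was.

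Genes were named by a fixed rule: among genes past the test, with a mean of at least 16 CPM in the higher group and library values that do not overlap between groups, the 8 largest fold changes per direction in the 4 classes with most cells, and 4 per direction in the other fits. Where fewer than 3 passed, the 3 smallest p-values were values only. Left out were genes without an HGNC-style symbol, variable segments of immunoglobulin and T cell receptor genes, HLA genes outside the lists, and genes that common deletions or variants change, RPS26 among them. FKBP5, TSC22D3, ZBTB16, PER1 and KLF9 in every tested class and the 3 leading members of each called list were added. RPS26 and AL139042.1 were named outside the rule, after their values were seen. Values of some list members are not reported here.

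The fits were tested on simulated counts with 200 genes changed by known amounts, drawn with the spread of each gene or with a spread that follows the mean. With 4-fold changes edgeR recovered 39% and 40% of genes for the T cell comparison, 54% and 62% for B cells, 68% and 72% for endothelial cells, 26% and 8% for stromal cells, and 29% and 49% for all cells. With 2-fold changes it recovered 0% and 2% for T cells, 2% and 1% for all cells, and at most 16% in any fit. The share of false calls was 22.0% and 2.33% for T cells and 20.5% and 0% for all cells. It was 6.78% and 2.63% for B cells, 2.27% and 3.70% for neutrophils and 13.5% and 4.60% for haematopoietic stem or progenitor cells. For endothelial cells it was 11.0% and 3.30%, and for pericytes or smooth muscle cells 10.0% and 7.22%. For cell numbers simulated with 8-fold changes in 4 of 18 classes, 0 of 4 were recovered. Leaving out each library, DESeq2, limma-voom, other size factors, no filter on low counts, a mitochondrial limit of 10%, kept doublets, equal cell numbers, other clusterings, stricter cell filters, fry, an estimated correlation and a block for the sample number were tried, and the closing section gives their effect. Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. These settings, lists, markers and alternatives were chosen before the data were examined, apart from the doublet score and the marker thresholds, which were set afterwards.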

Results

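Gene expression of single cells was measured in femoral heads labelled as steroid-induced osteonecrosis (ONFH, death of bone tissue; n = 2 libraries) or hip osteoarthritis (OA, degeneration of the joint; n = 3 libraries), with 1 library per labelled sample. The comparison of both diseases asks which cell types and which genes set ONFH apart from OA. Alcohol-induced osteonecrosis, which the series title also names, was not analysed here. The deposited values were counts of unique molecular identifiers (UMIs, counted transcript molecules). The totals were 62450342 and 23286947 UMIs in ONFH replicates 1 and 2 and 67997110, 70496767 and 59230736 in OA replicates 1, 2 and 3. After filtering, 7884 and 2048 ONFH cells and 7775, 15607 and 10866 OA cells were kept, with medians of 4289.5 and 7517 UMIs per cell in ONFH and 4908, 2979 and 3287 in OA. The labels do not say whether samples of a disease came from separate donors, so p-values for single genes and cell shares below measure the spread between these libraries. Camera p-values at the preset correlation of 0.01 compare the genes of a list with the other genes and do not measure that spread.

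Clustering gave 38 clusters, from which 18 classes were named by fixed marker genes. They were T-like, NK-like, B-like, B progenitor-like, plasma cell-like, monocyte-like, osteoclast-like, conventional dendritic cell-like, plasmacytoid dendritic cell-like, neutrophil-like, granulocyte-monocyte progenitor-like, haematopoietic stem or progenitor-like, erythroid-like, stromal-like, osteoblast-like, chondrocyte-like, endothelial-like and pericyte- or smooth muscle-like. The suffix is left out from here on. The largest part of the endothelial cells lay in cluster 20 in ONFH replicate 1 and in cluster 15 in the other libraries. Stromal cells lay mostly in cluster 19 in ONFH replicate 1 and in cluster 22 in the others. T cells were most numerous in cluster 11 in ONFH replicate 1, cluster 2 in ONFH replicate 2, cluster 0 in OA replicate 2 and cluster 3 in OA replicates 1 and 3. Most plasma cells lay in cluster 26 in ONFH replicate 1 and in cluster 9 elsewhere, and the largest part of the monocytes in cluster 4 in OA replicate 2 (45.4% of them) and in cluster 1 elsewhere (39.0% in ONFH replicate 2, where cluster 4 held 36.3%).

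Endothelial cells, which line blood vessels, made up 14.8% and 12.2% of kept cells in the ONFH libraries and 2.05%, 2.18% and 3.34% in the OA libraries. The means were 13.5% ± 1.85 (SD, n = 2) and 2.52% ± 0.713 (SD, n = 3). Neutrophils averaged 10.2% ± 5.34 in ONFH and 1.22% ± 1.69 in OA. The mean of stromal cells, which include the fibroblast-like support cells of marrow, was 8.78% ± 4.21 in ONFH and 1.31% ± 1.67 in OA. That of pericytes or smooth muscle cells, which wrap vessels, was 6.10% ± 5.04 and 1.30% ± 0.307. Monocytes averaged 6.83% ± 3.46 in ONFH and 20.9% ± 3.47 in OA, and B progenitors 0.755% ± 0.314 and 4.32% ± 1.67. The means were, in the same order of groups, for plasmacytoid dendritic cells 0.683% ± 0.553 and 4.56% ± 2.74, and haematopoietic stem or progenitor cells 1.15% ± 0.233 and 2.57% ± 0.886. The ranges of the groups did not overlap in these 8 of 18 classes, a separation that chance gives in 20% of classes. The two-sided exact permutation p was 0.2 for each, the smallest that 10 splits allow. For single libraries, the exact 95% Clopper-Pearson intervals, which cover counting error alone, ran from 14.0% to 15.6% and from 10.8% to 13.7% for endothelial cells in ONFH and at most to 3.70% in OA.

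No class passed the edgeR test of cell numbers with its adjustment over 18 classes (0 of 18; 4 had an unadjusted p under 0.05, and limma on centred log-ratios called 0). The log2 fold changes of those 4 classes were 2.42 (SE 0.69) for endothelial cells, 2.23 (SE 0.82) for pericytes or smooth muscle cells, -2.53 (SE 0.84) for B progenitors and -2.77 (SE 1.08) for plasmacytoid dendritic cells, each with an edgeR adjusted p of 0.180. Stromal cells had a log2 fold change of 2.74 (SE 1.25), monocytes -1.62 (SE 0.76) and neutrophils 3.08 (SE 1.69), with edgeR adjusted p-values of 0.190, 0.190 and 0.266. Leaving out single libraries moved these values. Pericytes or smooth muscle cells had 0.97 without ONFH replicate 2, neutrophils 5.34 without OA replicate 1 and stromal cells 4.63 without OA replicate 3. Without each library in turn, the lowest and highest values were 2.27 and 2.67 for endothelial cells, -3.02 and -2.14 for B progenitors, -3.96 and -2.09 for plasmacytoid dendritic cells and -2.25 and -1.17 for monocytes. With at least 1000 UMIs and 500 genes per cell, the log2 fold change of neutrophils was 5.42 (edgeR adjusted p = 0.0902). T cells made up 29.7% ± 7.64 of ONFH cells and 36.2% ± 6.11 of OA cells (exact permutation p = 0.4). Collagenase and dispase digestion, a Percoll density gradient, red cell lysis, a red cell antibody and a sort of live cells with DAPI preceded the libraries, per the labels' protocols, and each can set these shares. Without OA replicate 3 the same edgeR test called 2 classes, stromal cells and chondrocytes.

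**Figure D1:**
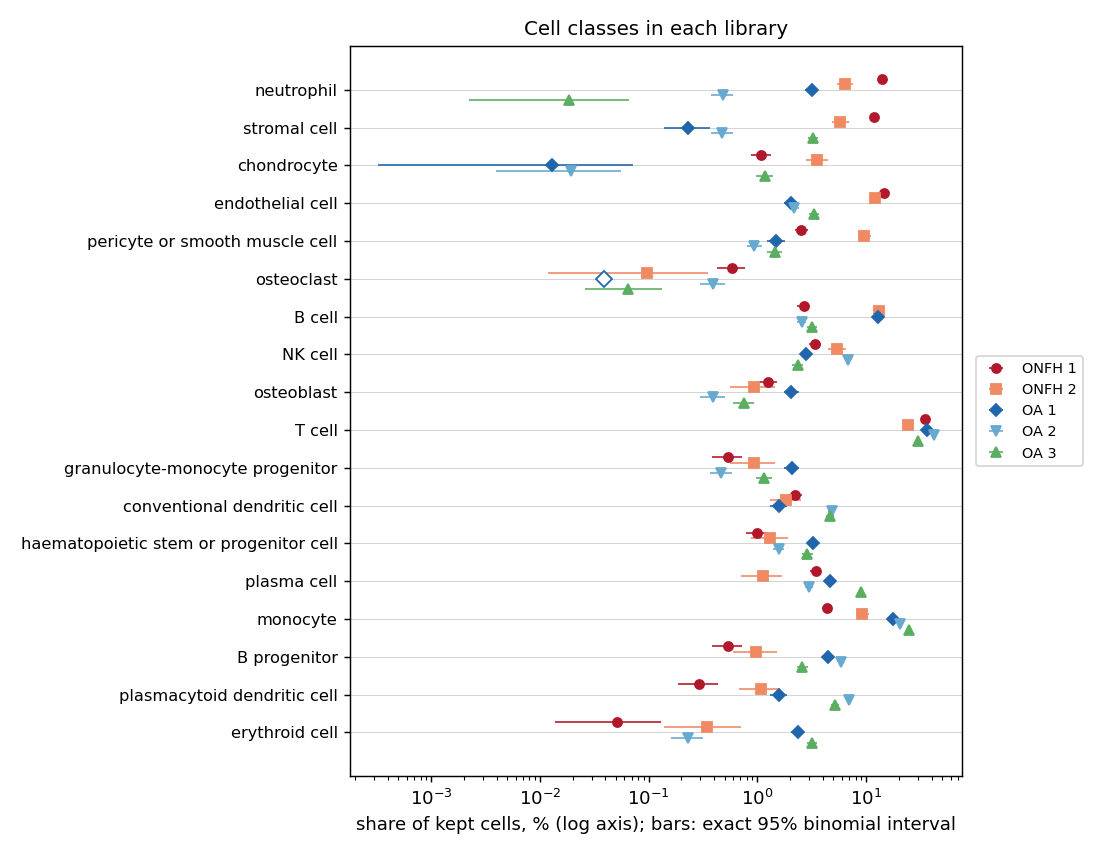
Share of kept cells in each of 18 cell classes (percent, log axis) for every library, with exact 95% binomial intervals as bars and an open symbol at the limit that a count of 0 allows. The endothelial cell shares of the ONFH libraries, 14.8% and 12.2%, lie above those of the OA libraries, 2.05% to 3.34%, while the monocyte shares lie below, at 4.39% and 9.28% against 17.7% to 24.6%.

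With all kept cells of a library summed, the fixed lists of secondary and tertiary neutrophil granule, cartilage matrix and angiogenesis genes were higher in ONFH and that of cell cycle genes lower by camera, each with an adjusted p = 0.772 with an estimated correlation. CAMP (ENSG00000164047, GRCh38 chromosome 3, 48223347 to 48225491), which encodes the antimicrobial peptide cathelicidin, averaged 151 ± 19.3 CPM, counts scaled to library size, in ONFH (SD, n = 2) and 2.07 ± 1.81 CPM in OA (SD, n = 3). Its log2 fold change was 6.18 (SE 1.06, edgeR adjusted p = 0.0461). PRG4 (ENSG00000116690, chromosome 1, 186296279 to 186314562), which encodes the joint lubricant lubricin, had a log2 fold change of 5.54 (SE 0.87, edgeR adjusted p = 0.0383). MMP8 (ENSG00000118113, chromosome 11, 102711795 to 102727050), a neutrophil collagenase, and S100A1 (ENSG00000160678, chromosome 1, 153627926 to 153632039), a calcium-binding protein gene, had log2 fold changes of 5.32 (SE 0.82) and 5.30 (SE 0.76). Lower in ONFH were DNTT (ENSG00000107447, chromosome 10, 96304396 to 96338564), the terminal transferase of early lymphocytes, with a log2 fold change of -3.82 (SE 0.40), and IGLL1 (ENSG00000128322, chromosome 22, 23573125 to 23580308), a part of the pre-B cell receptor, with -3.28 (SE 0.31). Both had an edgeR adjusted p of 0.0263. MYB (ENSG00000118513, chromosome 6, 135181315 to 135219173), a transcription factor of blood progenitors, averaged 24.8 ± 1.86 CPM in ONFH and 109 ± 49.0 CPM in OA, with a log2 fold change of -2.13 (SE 0.39). NBPF26, also called lower at -2.56 (SE 0.37), is a member of a family of near-identical copies and is therefore uncertain.

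The edgeR quasi-likelihood test called 646 of 23459 genes at an adjusted p of 0.05 over all cells, 589 higher and 57 lower in ONFH. The shares of neutrophils, endothelial cells and stromal cells averaged 10.2%, 13.5% and 8.78% in ONFH and 1.22%, 2.52% and 1.31% in OA. That of B progenitors averaged 0.755% and 4.32%. The count depended on the libraries and the tool: edgeR called 0 genes without ONFH replicate 1, without ONFH replicate 2 and without OA replicate 1, and 1102 without OA replicate 3. DESeq2 called 2705 genes, 1990 higher and 715 lower, which put 73.6% of its calls on the higher side where edgeR put 91.2%.

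Among the lists of genes fixed beforehand, the 16 collagen and fibrous matrix genes had a median log2 fold change of 3.54 over all cells (camera adjusted p = 4.18e-09; adjusted p = 0.772 with an estimated correlation). The edgeR test called 1 of them higher, LOX, a collagen cross-linking enzyme, at 3.17 (SE 0.62), and 16 higher and 0 lower when adjusted over the list alone. Of 16 cartilage matrix genes, 3 rose over all genes (11 higher, 0 lower when adjusted over the list alone), including CHAD at 3.35 (SE 0.46) and CNMD at 3.40 (SE 0.62). The list's camera adjusted p was 1.10e-08. Of 15 secondary and tertiary neutrophil granule genes, 5 rose (10 higher when adjusted over the list alone), among them CEACAM8 at 4.67 (SE 0.84) and CHI3L1 at 3.85 (SE 0.62), with a camera adjusted p of 1.15e-08. Of 17 angiogenesis genes, 5 rose and 1 fell (11 higher, 1 lower when adjusted over the list alone; camera adjusted p = 7.21e-04). The vascular receptors KDR and TEK rose by log2 3.65 (SE 0.39) and 2.83 (SE 0.32), and CDH5, the adhesion molecule of endothelial junctions, by 2.93 (SE 0.38). These genes are among the markers used to name endothelial cells, which averaged 13.5% of cells in ONFH and 2.52% in OA. Within classes camera called the angiogenesis list in 0 of 12 tests. The cartilage, granule and angiogenesis lists each had an adjusted p = 0.772 with an estimated correlation.

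Matrix degradation genes were also higher over all cells, with 6 of 19 called by edgeR (11 higher, 1 lower when adjusted over the list alone). Among them were the aggrecan-cleaving protease gene ADAMTS5 at log2 3.16 (SE 0.56) and ADAMTS1 at 2.25 (SE 0.31). The list's camera adjusted p was 5.57e-05. In the osteoblast list, 1 of 15 genes rose (10 higher, 1 lower when adjusted over the list alone; camera adjusted p = 1.24e-04). It was BGLAP, which encodes the bone matrix protein osteocalcin, at 2.19 (SE 0.38). IBSP, which encodes bone sialoprotein, had 3.67 (SE 0.81, edgeR adjusted p = 0.0697). Each of the 18 cell cycle genes had a negative log2 fold change, with a median of -1.31 (camera adjusted p = 4.18e-09). The proliferation marker MKI67 fell, at -1.44 (SE 0.23, edgeR adjusted p = 0.0360), as 1 of 18 over all genes and 14 of 18 when adjusted over the list alone. All 3 of these lists had an adjusted p = 0.772 with an estimated correlation. The 10 haemoglobin and late erythroid genes had a median of -3.71 (camera adjusted p = 9.40e-05; adjusted p = 0.862 with an estimated correlation). Of them edgeR called 0, over all genes or adjusted over the list alone. Erythroid cells, which the red cell antibody and lysis can remove, averaged 0.196% ± 0.206 in ONFH and 1.92% ± 1.52 in OA.

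The NF-kB inflammatory list was lower over all cells, with a median log2 fold change of -0.81 over 24 genes (camera adjusted p = 0.00333; adjusted p = 0.902 with an estimated correlation). None of the list's members passed edgeR over all genes or adjusted over the list alone. CXCL8, a chemokine that attracts neutrophils, averaged 756 ± 32.7 CPM in ONFH and 1492 ± 387 CPM in OA. Monocytes made up 6.83% of ONFH cells and 20.9% of OA cells, and CXCL8 was among the leading genes of monocyte cluster 4. The members did not all go one way: ICAM1, an adhesion molecule, had a log2 fold change of 1.07 (SE 0.33). The call ended without OA replicate 2 (camera adjusted p = 0.0524). The 11 MHC class II presentation genes had a median of -0.39 (camera adjusted p = 0.0461; adjusted p = 0.772 with an estimated correlation). The call ended without each library in turn. Its camera adjusted p-values were 0.0795 without ONFH replicate 1, 0.0581 without ONFH replicate 2, and 0.0584, 0.0680 and 0.0623 without OA replicates 1, 2 and 3.

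Within cell classes, the gene called in most classes was SLC35F1 (ENSG00000196376, GRCh38 chromosome 6, 117907526 to 118317676), a member of a solute carrier family. Its level in B cells was 111 ± 23.4 CPM in ONFH (SD, n = 2) and 10.8 ± 1.92 CPM in OA (SD, n = 3). The log2 fold change was 3.40 (SE 0.37, edgeR adjusted p = 0.00683). In haematopoietic stem or progenitor cells it had a log2 fold change of 4.81 (SE 0.38, edgeR adjusted p = 0.00333), and in endothelial cells 3.81 (SE 0.43, edgeR adjusted p = 0.0481). SLC35F1 UMIs were found in 24.6% and 28.3% of ONFH T cells (medians of 3177 and 5133.5 UMIs) and in 1.05%, 1.69% and 1.05% of OA T cells (3970.5, 2326 and 2219 UMIs). In ONFH neutrophils, at medians of 1908.5 and 6718.5 UMIs, they were in 3.71% and 3.03%. The library values did not overlap in 12 of 13 tested classes, which are not independent because they come from the same 5 libraries, and the exception was neutrophils. Leaving out OA replicate 3 ended the B cell call (edgeR adjusted p = 0.0612), and leaving out OA replicate 1 the stem or progenitor cell call (0.0745). In endothelial cells it ended without ONFH replicate 1 (0.0688) and without OA replicates 1, 2 and 3 (0.313, 0.0508 and 0.169).

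CLU (ENSG00000120885, chromosome 8, 27596917 to 27615031), which encodes the secreted chaperone clusterin, was higher in ONFH B cells, at 65.2 ± 2.20 CPM against 4.08 ± 2.41 CPM in OA. Its log2 fold change was 4.33 (SE 0.55, edgeR adjusted p = 0.0151; 0.0612 without OA replicate 3). CLU UMIs were in 23.8% and 32.3% of ONFH B cells (medians of 3939.5 and 6015 UMIs) but also in 26.9% and 29.5% of ONFH T cells and in 25.3% and 25.8% of ONFH neutrophils, at the depths given above. Levels were 66.9 and 59.4 CPM in ONFH B cells, 97.1 and 68.2 CPM in T cells, 140 and 47.3 CPM in neutrophils and 2184 and 4556 CPM in stromal cells. The B cell values therefore lay at background and are not read as expression by B cells. In endothelial cells, PDE1C (ENSG00000154678, chromosome 7, 31751179 to 32299329), a phosphodiesterase of cyclic nucleotides, averaged 37.7 ± 11.9 CPM in ONFH and 2.90 ± 0.782 CPM in OA. The fitted log2 fold change was 3.71 (SE 0.42, edgeR adjusted p = 0.0481). Its call ended without ONFH replicate 1 (0.131) and without OA replicates 1, 2 and 3 (0.313, 0.0832 and 0.169). ITGBL1 (ENSG00000198542, chromosome 13, 101452593 to 101720856), an integrin beta-like gene, averaged 127 ± 34.7 CPM in ONFH pericytes or smooth muscle cells and 7.60 ± 1.04 CPM in OA. There the log2 fold change was 4.05 (SE 0.38, edgeR adjusted p = 0.00545). The ITGBL1 call ended without OA replicate 2 (0.0515), and limma-voom gave it an adjusted p of 0.281. RPS26, a ribosomal protein gene named after its values were seen, was lower in B cells (log2 -3.16, SE 0.42, edgeR adjusted p = 0.0151).

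Neutrophils, tested in 2 ONFH and 2 OA libraries, had 6 genes lower in ONFH and 0 higher. The 4 under the naming rule were LEF1 (ENSG00000138795), a transcription factor of T cells, CAMK4 (ENSG00000152495), a calcium-dependent kinase, IL7R (ENSG00000168685), the receptor of interleukin 7, and NELL2 (ENSG00000184613). Their log2 fold changes were -5.30 (SE 0.64), -4.20 (SE 0.57), -4.63 (SE 0.63) and -5.16 (SE 0.75), with edgeR adjusted p-values of 0.0279, 0.0302, 0.0302 and 0.0479. The summed level of these 4 genes in neutrophils was 3.50% and 1.24% of the T cell level in the ONFH libraries and 18.4% and 39.4% in OA replicates 1 and 2. That of 12 T cell markers, which include IL7R, was 3.31% and 1.07% against 15.3% and 27.5%. The 4 genes thus moved with the T cell markers, and their calls are not read as a change within neutrophils. OA neutrophils had medians of 654 and 931 UMIs. RPS26 and the noncoding AL139042.1, named after their values were seen, were also lower. RPS26 had a log2 fold change of -3.06, while AL139042.1 had 0 UMIs in ONFH, which allows up to 3 over the group, and 21 in OA, at 79.0 ± 14.3 CPM (SD, n = 2). Without OA replicate 2, edgeR called 1 gene, and the adjusted p of LEF1, CAMK4, IL7R and NELL2 was 0.121, 0.121, 0.107 and 0.139. Without ONFH replicates 1 and 2 and OA replicate 1 it called 53, 36 and 12 genes. With called doublets kept, with equal numbers of cells and at clustering resolution 2, edgeR called 0 neutrophil genes, with 638, 209 and 447 at an unadjusted p under 0.05, while DESeq2 and limma-voom with the original cells called 70 and 5.

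In all, edgeR called 13 gene and class pairs in 13 tested classes, 6 higher and 7 lower. It called 0 genes in T cells, NK cells, B progenitors, plasma cells, monocytes, conventional and plasmacytoid dendritic cells and stromal cells. In that order 709, 295, 864, 744, 906, 602, 430 and 690 genes had an unadjusted p under 0.05. For these classes DESeq2 called 79, 7, 37, 46, 58, 39, 2 and 27 genes, and limma-voom 0 in each. Values in those classes that did not pass included SLC35F1 at log2 3.87 (edgeR adjusted p = 0.0729) and LTF, which encodes the granule protein lactoferrin, at 4.10 (0.0899) in T cells. LTF UMIs were in 6.97% and 6.83% of ONFH T cells, below the 9.05% and 9.67% of ONFH B cells (medians of 3939.5 and 6015 UMIs), and are read as background. In ONFH neutrophils they were in 77.4% and 88.6%, at 4799 and 7619 CPM against 21.5 and 13.9 CPM in T cells. Monocytes had TMEM176B at 4.86 and COL24A1 at -2.65, and stromal cells had the lubricin gene PRG4 at 4.09 and GREM1, an antagonist of bone morphogenetic proteins, at 3.72 (edgeR adjusted p = 0.648). Single libraries moved the counts. Over the 13 classes edgeR called 117 and 582 pairs without ONFH replicates 1 and 2 and 28 without OA replicate 1. Among them were 25 and 503 stromal cell genes without ONFH replicates 1 and 2. Without OA replicate 2 it called 10 T cell genes.

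**Figure D2:**
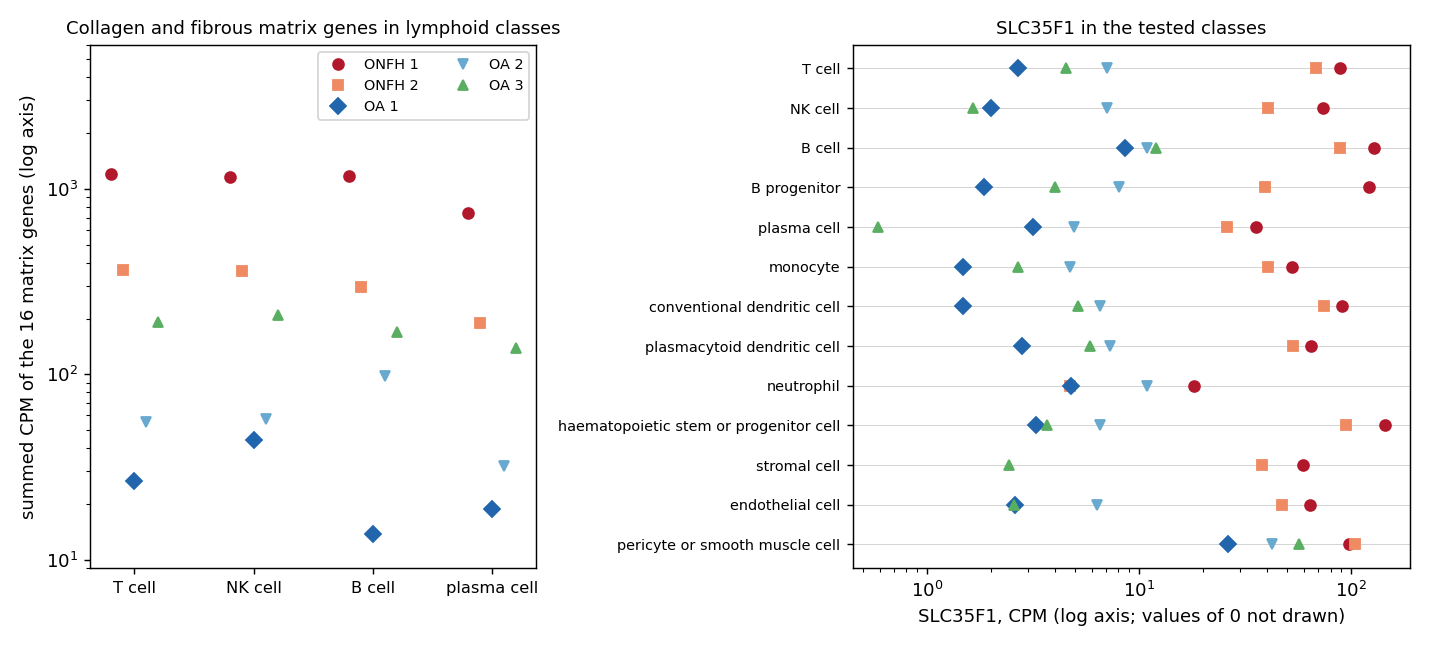
Left, summed CPM (log axis) of the 16 collagen and fibrous matrix genes in 4 lymphoid classes of every library; right, SLC35F1 CPM (log axis, values of 0 not drawn) in the 13 tested classes. In T cells the matrix genes sum to 1203 and 367 CPM in ONFH and 26.6, 55.4 and 192 CPM in OA, and SLC35F1 lies at 88.9 and 68.6 CPM in ONFH and 2.68 to 7.04 CPM in OA.

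Camera called the collagen and fibrous matrix list higher in all 13 tested classes, with medians from 1.13 in stromal cells to 3.86 in neutrophils. Each call had an adjusted p = 0.853 with an estimated correlation, and all 13 held in every fit without a library that could be run (largest camera adjusted p 0.00377). The neutrophil call had no test without ONFH replicate 1. Neutrophils were compared without OA replicate 3 and stromal cells without OA replicate 1, so leaving these out is no test there. The median log2 fold change was 2.85 in T cells (15 genes; camera adjusted p = 1.78e-17), 2.06 in pericytes or smooth muscle cells (16 genes; 1.78e-17), 1.86 in endothelial cells (14 genes; 1.10e-07) and 1.13 in stromal cells (16 genes; 2.52e-06). Over the list alone, edgeR called 10, 15, 3 and 1 of these genes higher and 0 lower, and over all genes 0 in each. In pericytes or smooth muscle cells COL6A3 had a log2 fold change of 2.86 and COL5A2 2.13, and in stromal cells POSTN, a matrix protein of bone surfaces, had 2.57 and COL1A1 1.92. COL1A1 was among the leading genes of stromal clusters 19 and 29. Cluster 19 held 589 of 927 and 43 of 119 stromal cells in ONFH, and 5 of 74 and 110 of 351 in OA replicates 2 and 3. Of the 195 cells in cluster 29, 194 came from ONFH replicate 1. A shift between clusters was not told apart from a change within stromal cells. No background share was computed for pericytes or smooth muscle cells, so RNA of other cells was not told apart from their own. COL1A1 UMIs, from the main collagen of bone, were in 62.7% and 30.5% of ONFH T cells and in 1.47%, 3.42% and 8.22% of OA T cells. Of ONFH stromal cells 98.9% and 95.8% held them. Summed over the list, the T cell level was 4.16% and 2.01% of that in stromal, bone, cartilage and vessel cells of the same ONFH library and 0.917%, 0.864% and 1.11% in OA.

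The list of osteoblast genes was higher by camera in 11 of 13 classes, 5 of which held in every fit without a library, and that of cartilage matrix genes in 5 of 5 tested, 3 of which held. Matrix degradation genes were higher by camera in 7 of 12 classes. Each call of this paragraph had an adjusted p = 0.853 with an estimated correlation, and edgeR called 0 of the members over all genes. The osteoblast calls included T, B and NK cells and the cartilage calls T cells and monocytes, which are not known to make these genes, and are not read as expression by those cells. The matrix degradation calls that held in every fit without a library were those of stromal cells (median log2 0.78 over 17 genes, camera adjusted p = 3.32e-05) and of pericytes or smooth muscle cells (0.65 over 13 genes, 0.00515). In stromal cells the collagenase gene MMP1 had a log2 fold change of 3.75 and MMP13 2.39, with 6 genes higher and 0 lower when adjusted over the list alone. MMP13 was also among the leading genes of stromal clusters 19 and 29, whose uneven shares of stromal cells are given above. Pericytes or smooth muscle cells also had higher coagulation and fibrinolysis genes (median 0.97 over 11 genes, camera adjusted p = 9.36e-04; 5 higher, 1 lower when adjusted over the list alone). PLAT, the tissue plasminogen activator, had a log2 fold change of 1.60. Complement genes were higher there too (median 1.20 over 7 genes, camera adjusted p = 7.43e-04), with C1S at 1.20. Stromal cells averaged 8.78% of ONFH cells and 1.31% of OA cells, and no background share was computed for pericytes or smooth muscle cells. RNA of other cells was therefore not told apart from their own in these calls. Without ONFH replicate 1, 5 osteoblast calls and 4 matrix degradation calls ended.

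The list of cell cycle genes was called by camera in 7 of 10 classes, 2 up and 5 down, each with an adjusted p = 0.853 with an estimated correlation. It was higher in endothelial cells, where 11 of 11 measured had a positive log2 fold change (median 0.89, camera adjusted p = 1.03e-07; 5 higher when adjusted over the list alone), including CENPF at 1.98 and MKI67 at 1.73. It was lower in B progenitors (median -1.36 over 18 genes, camera adjusted p = 3.53e-08; 10 lower when adjusted over the list alone), including the cyclin-dependent kinase gene CDK1 at -2.70 and NUSAP1, a mitotic spindle protein gene, at -1.22. It was also lower in NK cells (median -0.85 over 7 genes, 9.06e-05), and the other 4 calls each ended without at least 1 library. Oxidative phosphorylation genes of the respiratory chain were higher by camera in stromal cells, with 31 of 31 positive (median 0.57, camera adjusted p = 3.96e-07) and UQCR11 at 1.25. They were lower in monocytes (median -0.37, 4.54e-04), with COX4I1 at -0.68. Heat shock genes were lower by camera in plasma cells (median -1.05 over 12 genes, camera adjusted p = 1.88e-04), with HSPH1 at -1.76. They were also lower in conventional dendritic cells (0.00236; 0.367 without ONFH replicate 2 and 0.0604 without OA replicate 1) and higher in haematopoietic stem or progenitor cells (0.0359; 0.714 without ONFH replicate 2 and 0.448 without OA replicate 3). The calls given for oxidative phosphorylation and heat shock genes also had an adjusted p = 0.853 with an estimated correlation, and the 6 calls given with a median held in every fit without a library. Most endothelial and stromal cells of ONFH replicate 1 lay in clusters 20 and 19, and most of those of the other libraries in clusters 15 and 22. Cluster 23, led by DNTT, held 9 of 42 and 2 of 20 B progenitors in ONFH and 79 of 346, 275 of 924 and 132 of 281 in OA. Cluster 26 held 222 of 273 plasma cells in ONFH replicate 1, and ONFH replicate 2 had 23 plasma cells. A shift between clusters was not told apart from a change within these classes. Whether the cell cycle changes differ between endothelial cells and B progenitors was not tested.

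Camera called the list of glucocorticoid-induced genes lower in ONFH in 8 of 13 classes, mainly through 1 library. No such call remained with an estimated correlation, and no member passed edgeR over all genes in any class. FKBP5, which encodes a co-chaperone of the glucocorticoid receptor and is induced by it, lay at 129 and 1084 CPM in T cells of ONFH replicates 1 and 2 and at 953, 1434 and 1695 CPM in OA. This was a log2 fold change of -1.34 (SE 0.87). TSC22D3, which encodes the glucocorticoid-induced leucine zipper, had log2 fold changes of -0.95 in T cells, -1.35 in monocytes and -2.12 in neutrophils. Neither FKBP5 nor TSC22D3 passed the edgeR test in any class or over all cells. In both ONFH libraries TSC22D3 was below all OA libraries in monocytes (84.2 and 206 against 262 to 370 CPM) and endothelial cells (118 and 186 against 223 to 251 CPM). The same held in pericytes or smooth muscle cells (153 and 272 against 373 to 407 CPM) and neutrophils (67.5 and 235 against 769 and 500 CPM). In neutrophils the OA barcodes held more T cell RNA, as given above. The groups overlapped in the other tested classes. In T cells ONFH replicate 2, at 937 CPM, lay within the OA range of 728 to 1382 CPM. Over FKBP5, TSC22D3, ZBTB16, PER1 and KLF9, ONFH replicate 2 was below all OA libraries in 11 of 65 gene and class pairs. The list of 19 genes had negative medians in 13 of 13 classes. It fell in T cells (median -0.62, camera adjusted p = 0.00124), B cells (-0.45, 0.00393), endothelial cells (-0.46, 9.38e-04) and monocytes (-0.48, 0.00733). Each had an adjusted p = 0.853 with an estimated correlation. The calls in pericytes or smooth muscle cells, conventional dendritic cells, plasma cells and haematopoietic stem or progenitor cells had camera adjusted p-values of 0.0209, 0.0267, 0.0382 and 0.0470 and the same p with an estimated correlation. All 8 calls ended without ONFH replicate 1, at camera adjusted p-values from 0.108 to 0.975, and 0 ended without ONFH replicate 2. Without OA replicates 1, 2 and 3 there ended 3, 2 and 5, at p-values up to 0.103, 0.127 and 0.345. The labels give no dose or timing of steroid treatment.

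**Figure D3:**
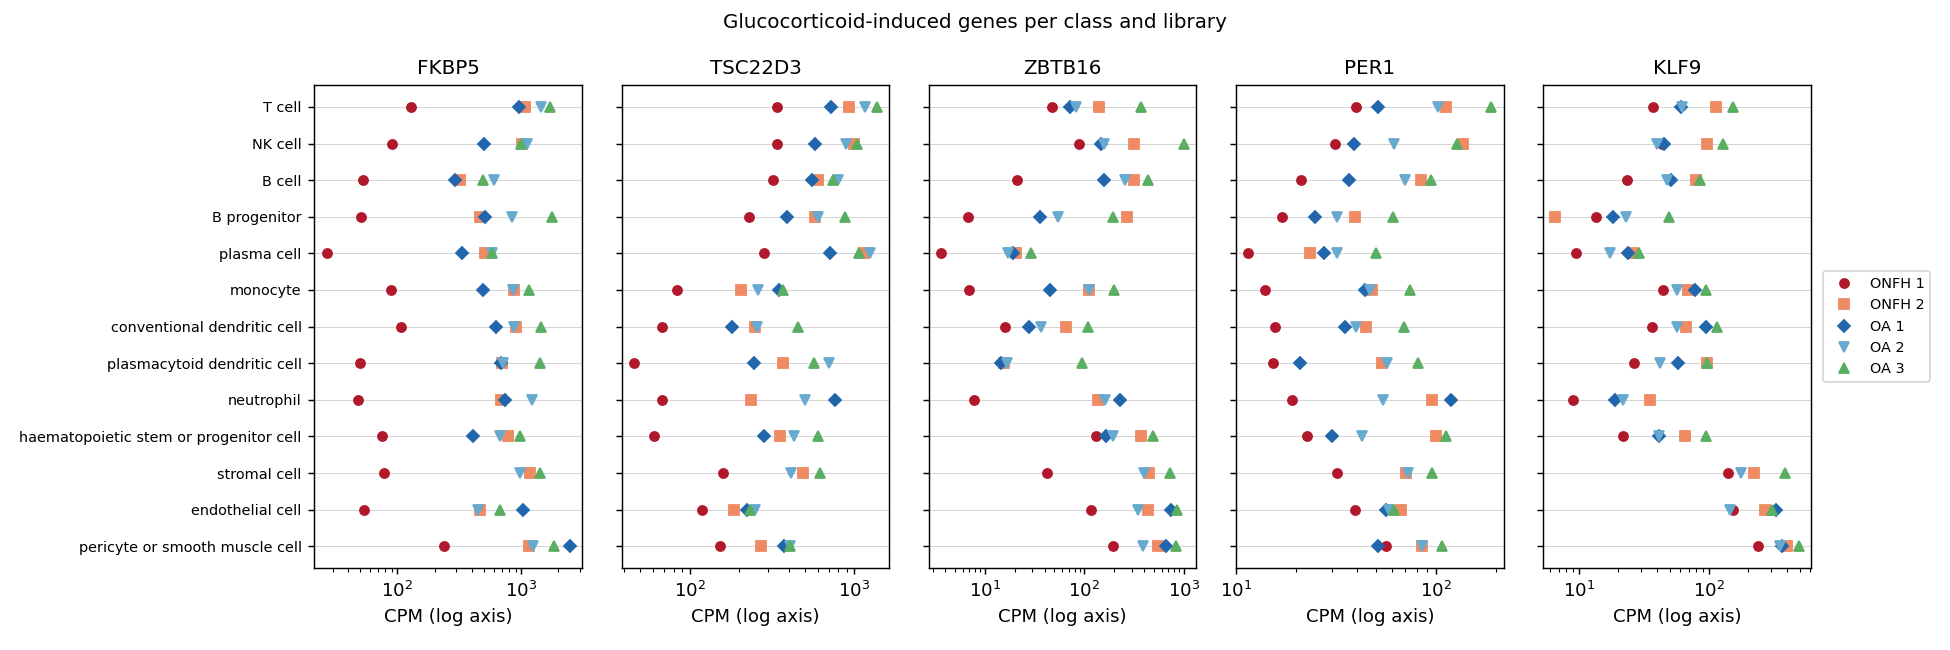
Level of 5 glucocorticoid-induced genes (CPM, log axis) in each tested class of every library, 1 symbol per library. In T cells FKBP5 lies at 129 CPM in ONFH replicate 1, below ONFH replicate 2 at 1084 CPM and the OA libraries at 953 to 1695 CPM.

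Every camera call in this paragraph had an adjusted p = 0.853 with an estimated correlation, and edgeR called 0 of the members over all genes. Secondary and tertiary granule genes of neutrophils were higher by camera in T cells (median log2 3.86 over 6 genes, camera adjusted p = 1.55e-08), plasma cells (3.94 over 5 genes, 4.54e-04) and stromal cells (2.04 over 7 genes, 0.00736; 0.0725 without ONFH replicate 1). Neutrophils made up 10.2% of ONFH cells and 1.22% of OA cells, and LTF, a member of the list, was at background in T cells. Within neutrophils the secondary and tertiary granule genes had a median of 0.68 over 15 genes (camera adjusted p = 0.00739), with CAMP at 1.96 and MMP8 at 1.43. That call ended without ONFH replicate 2 (0.0544) and without OA replicate 2 (0.590). OA neutrophils held T cell markers at 15.3% and 27.5% of the T cell level, against 3.31% and 1.07% in ONFH. RNA of other cells in OA neutrophil barcodes would lower granule gene levels there. It was not told apart from a change within neutrophils. Haemoglobin and late erythroid genes were lower by camera in 5 of 5 classes tested, with a median of -3.12 in T cells (8 genes, camera adjusted p = 4.48e-06). HBB UMIs, from the beta chain of haemoglobin, were in 1.05% and 7.23% of ONFH T cells and in 34.1%, 2.47% and 19.6% of OA T cells, at the T cell depths given above. B cells held them in 0% (0 of 210 cells, which allows 1.43%) and 5.58% in ONFH and in 38.4%, 1.75% and 18.6% in OA, at medians of 3939.5, 6015, 4483, 2070 and 2422 UMIs. Erythroid cells made up 0.0507% and 0.342% of cells in ONFH and 2.35%, 0.231% and 3.18% in OA, and the T and B cell shares are read as background. MHC class II presentation genes, with a median of -0.39 over all cells, were higher by camera in conventional dendritic cells, with 11 of 11 positive (median 0.52, camera adjusted p = 8.66e-04, adjusted p = 0.853 with an estimated correlation; 0.188 without ONFH replicate 1). They were also higher in plasmacytoid dendritic cells (0.00206; 0.0524 and 0.109 without ONFH replicates 1 and 2). Type I interferon response genes were lower by camera in 3 of 13 classes, T cells (0.0135), stromal cells (median -1.14 over 19 genes, camera adjusted p = 0.00232) and endothelial cells (-0.87 over 21 genes, 0.00562), with the antiviral gene IFI44L at -3.37 and -2.23 in the latter classes. Without OA replicate 2 the interferon calls ended, at 0.890, 0.648 and 0.979. The T cell call also ended without ONFH replicates 1 and 2 (0.0528 and 0.0784), and the endothelial call without ONFH replicate 2 (0.0651). NF-kB inflammatory genes were lower by camera in 6 of 13 classes, B cells (0.00467), T cells (0.00562), monocytes (0.0140), endothelial cells (0.0200), neutrophils (0.0241) and NK cells (0.0475). Each of these calls ended without at least 2 of the libraries in turn, at p-values up to 0.668. RNA of other cells in OA neutrophil barcodes also limits the neutrophil call.

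Across 13 classes, 99 of 351 list tests were called by camera, 53 up and 46 down. Of these, 38 held in every fit without a library that could be run, and 38, 28, 15, 22 and 26 ended without ONFH replicates 1 and 2 and OA replicates 1, 2 and 3. Among the 38, some lists had too few measured members in part of the 5 fits. Haemoglobin and late erythroid genes had 3 fits in monocytes and 2 in plasmacytoid dendritic cells, and secondary and tertiary granule genes 3 in plasma cells. In neutrophils, collagen and fibrous matrix genes had fits without ONFH replicate 2 and without OA replicates 1 and 2. Counted fits without OA replicate 3 in neutrophils and without OA replicate 1 in stromal cells left out no library of that comparison. They repeat the main fit and are no test. With a correlation estimated from the data camera called 0 of the 351 tests, 10 of which had an unadjusted p under 0.05. Fry, which tests whether a list's genes move on balance one way, called 0, with 24 at an unadjusted p under 0.05. Over all cells both also called 0 of 32 lists, with 1 and 7 lists at an unadjusted p under 0.05.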

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

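All alternatives here were planned. Of 6465 values of named genes under an alternative, 5828 kept their direction and their side of the threshold. The call was lost in 122 and gained in 441. Another 74, which were not past the test in the main fit, changed direction, and 0 called values reversed. Of 231 class shares, 212 kept their direction and their side, 4 gained a call, and 15 without a call in the main fit changed direction. Of 1064 list tests, 673 kept their side, 382 lost the call and 9 reversed. Of 247 counts and other summaries, 129 stayed within 1.5 times, with the others given below. For those the cause was not tested, which includes the list calls lost with an estimated correlation. With 2 ONFH libraries, a fit without either assumes that the lone ONFH library varies like the OA libraries. Neutrophils and stromal cells, tested in 2 libraries per group, can also keep a lone OA library. This holds without OA replicates 1 or 2 in neutrophils and without OA replicates 2 or 3 in stromal cells. Plasmacytoid dendritic cells had as few as 22 cells in a library, and 0% and 11% of 4-fold changes simulated in them were recovered. B progenitors and plasma cells had as few as 20 and 23 cells, with 27% and 48%, and 26% and 45%, recovered.

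DESeq2 called 2705 genes over all cells, where edgeR called 646, and 586 over the 13 classes, where edgeR called 13. By class it called 79 in T cells, 7 in NK cells, 29 in B cells, 37 in B progenitors, 46 in plasma cells, 58 in monocytes, 39 in conventional and 2 in plasmacytoid dendritic cells, 70 in neutrophils, 20 in haematopoietic stem or progenitor cells, 27 in stromal cells, 89 in endothelial cells and 83 in pericytes or smooth muscle cells. With no filter on low counts edgeR called 1078 genes over all cells and 1990 over the classes, which in the same order of classes were 230, 50, 102, 163, 225, 32, 152, 31, 121, 101, 148, 278 and 357. With limma-voom the counts were 1146 over all cells, 0 in endothelial cells and 0 in pericytes or smooth muscle cells. With DESeq2's size factors in edgeR, and with cells under 10% mitochondrial counts, the endothelial count of 2 became 0.

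With called doublets kept, edgeR called 25 genes over the classes, among them 1 in conventional dendritic cells, 0 in neutrophils, 1 in endothelial cells and 19 in pericytes or smooth muscle cells. With equal numbers of cells per library it called 33, with 2 in T cells, 6 in B cells, 8 in B progenitors, 2 in plasma cells, 5 in conventional dendritic cells, 0 in neutrophils, 5 in haematopoietic stem or progenitor cells and 2 in pericytes or smooth muscle cells. At resolution 2 it called 5, with 1 in T cells, 1 in B cells and 0 in neutrophils. With each library clustered on its own it called 1 gene in T cells, 1 in B cells, 3 in stromal cells, 0 in endothelial cells and 3 in pericytes or smooth muscle cells, and 1 class share.

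A fit with the sample number as a replicate block called 1386 genes over all cells and 679 over the classes, with 1 in T cells, 1 in NK cells, 13 in B cells, 74 in B progenitors, 129 in plasma cells, 20 in monocytes, 232 in neutrophils, 8 in haematopoietic stem or progenitor cells, 201 in endothelial cells and 0 in pericytes or smooth muscle cells, and 1 class share. No such fit was possible in stromal cells, where too few numbers were shared by both groups. It called 11 lists over all cells, 9 of them shared with the 10 of the fit without the block, and 92 class lists, 72 of them shared with 99. The numbers name samples of different diseases and pair nothing, so this is a change of the fit and not of the design. Across 20136 genes, which are not independent replicates, deviations from the group means of same-numbered libraries had a correlation of 0.135 for number 1 and 0.258 for number 2, and 0.187 for ONFH replicate 1 with OA replicate 3, whose numbers differ. With 2 ONFH libraries the values of one are those of the other with the sign turned, so the correlations do not establish a pairing.

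With an estimated correlation, and with fry, 0 lists were called over all cells and 0 in the classes. Without 1 library at a time, edgeR called 0 to 1102 genes over all cells (0 without ONFH replicate 1, ONFH replicate 2 or OA replicate 1, and the highest count without OA replicate 3) and 18 to 582 over the classes (the highest without ONFH replicate 2, the lowest without OA replicate 2). By class the ranges were 0 to 10 in T cells, 0 to 1 in NK cells, 1 to 20 in B cells, 0 to 2 in B progenitors, 0 to 1 in plasma cells, 0 to 1 in monocytes, 0 to 2 in conventional and 0 to 2 in plasmacytoid dendritic cells, 1 to 53 in neutrophils, 0 to 11 in haematopoietic stem or progenitor cells, 0 to 503 in stromal cells, 0 to 11 in endothelial cells and 0 to 21 in pericytes or smooth muscle cells. Class shares gave 0 to 2 calls, with 2 only without OA replicate 3. Lists gave 9 to 15 calls over all cells and 83 to 114 in the classes.

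The direction of 9 list calls reversed without a library. Their camera adjusted p-values over these fits ranged from 1.29e-04 to 0.890 for type I interferon genes in T cells and from 2.68e-09 to 0.648 in stromal cells, both reversed without OA replicate 2. Immunoglobulin constant genes ranged from 5.60e-08 to 0.392 in T cells, from 7.44e-11 to 0.998 in monocytes and from 2.57e-06 to 0.157 in haematopoietic stem or progenitor cells, all reversed without ONFH replicate 2. Also reversed without ONFH replicate 2 were complement genes in haematopoietic stem or progenitor cells (7.20e-05 to 0.909) and primary neutrophil granule genes in stromal cells (0.00257 to 0.924). Reversed without ONFH replicate 1 were glucocorticoid response genes in conventional dendritic cells (2.22e-06 to 0.975) and cell cycle genes in stromal cells (1.75e-06 to 0.727).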

Other observations

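The tests of explanations in the last 3 paragraphs were chosen after the results were seen, while the tests of shares and lists were planned. Bone and cartilage cells were few in every library. Osteoblasts made up 1.09% ± 0.232 of kept cells in ONFH (SD, n = 2) and 1.07% ± 0.877 in OA (SD, n = 3; exact permutation p = 1), osteoclasts 0.341% ± 0.344 and 0.152% ± 0.210 (p = 0.4 by the same exact test), and chondrocytes 2.33% ± 1.75 and 0.400% ± 0.666 (exact permutation p = 0.4). Most chondrocytes lay in cluster 30 except in OA replicate 3, where cluster 31 held most. NK cells made up 4.41% ± 1.43 and 4.02% ± 2.49 (exact permutation p = 1), B cells 7.90% ± 7.40 and 6.20% ± 5.78 (0.8), plasma cells 2.29% ± 1.65 and 5.58% ± 3.14 (0.4), conventional dendritic cells 2.04% ± 0.258 and 3.68% ± 1.83 (0.6), and granulocyte-monocyte progenitors 0.730% ± 0.279 and 1.24% ± 0.811 (0.6). The 4 unnamed clusters held 0.952% ± 0.863 of cells in ONFH and 0.873% ± 0.481 in OA. The largest of them, with 238 cells, had ITGA2B, a platelet integrin, among its leading genes, and 24 of the 25 cells of another, led by RBFOX1, came from ONFH replicate 2.

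Several other lists were called by camera in a few classes, each with an adjusted p = 0.853 with an estimated correlation. Primary neutrophil granule genes were lower in conventional dendritic cells (median log2 -1.74 over 6 genes, camera adjusted p = 8.48e-06; 3 lower when adjusted over the list alone), with MPO, the granule peroxidase, at -2.41, and in endothelial cells (-1.74 over 5 genes, 6.83e-04), and these calls held in every fit without a library. They were also lower in plasma cells (0.00129; 0.0604 without ONFH replicate 1) and stromal cells (0.0189; 0.924 without ONFH replicate 2 and 0.783 without OA replicate 3). No background share was computed in these 4 classes, so expression by these cells was not told apart from RNA of other cells. In neutrophils the primary granule genes were higher (0.0426), a call that ended without ONFH replicate 2 and without OA replicates 1 and 2 (0.120, 0.126 and 0.208). RNA of other cells in OA neutrophil barcodes was not told apart from a change within neutrophils. Over all cells the primary granule and mature neutrophil lists were not called (camera adjusted p = 0.738 and 0.661). Cholesterol synthesis genes were lower in 4 of 13 classes, with a median of -0.39 over 14 genes in conventional dendritic cells (camera adjusted p = 0.0135), and all 4 calls ended without OA replicate 3, at p-values from 0.103 to 0.209. Immunoglobulin constant genes were lower in 4 of 13 classes, none of which is known to make them, with a median of -1.10 in monocytes (0.00354). All 4 calls ended without ONFH replicate 2, at 0.157 to 0.998, and are not read as expression by those classes. Plasma cells averaged 2.29% of ONFH cells and 5.58% of OA cells. Camera called 0 tests, of 104 over the tested classes, for 10 lists (hypoxia response, glycolysis, angiogenesis, adipogenesis and lipid storage, p53 and apoptosis, osteoclast, cytotoxicity, T cell inhibitory receptors, mitochondrially encoded and platelet genes); 9 had an unadjusted p under 0.05, the smallest adjusted p was 0.0526, and fry and an estimated correlation also called 0.

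The list of collagen and fibrous matrix genes was higher by camera in ONFH lymphocytes, which are not known to make them, with an adjusted p = 0.853 with an estimated correlation and 0 members called by edgeR over all genes in T cells. Doublets with matrix-producing cells would give COL1A1 UMIs to few T cells, but 30.5% or more of T cells held one in both ONFH libraries. Expression by the lymphocytes themselves might differ between their types. The summed level of the list differed by at most 1.24-fold between T, NK and B cells within an ONFH library. Expression at a like level in these types would give the same, so it is not excluded. Plasma cells, up to 1.94-fold below T cells in CPM, stay open. They held 3686 and 73 UMIs of the list in 273 and 23 cells of ONFH replicates 1 and 2, and T cells 11486 and 980 in 2769 and 498. Plasma cells thus held more per cell, which free RNA spread evenly over droplets would not give alone. Free RNA from matrix-producing cells is a candidate explanation: across the 16 genes, which are not independent replicates, T cell levels followed those of the library's own stromal, bone, cartilage and vessel cells, with Pearson r of 0.953 or more on the log2 scale in both ONFH libraries. A disease difference in the matrix-producing cells, or in how many broke during digestion, stays open and was not tested.

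SLC35F1 was higher in ONFH in most classes. Free RNA reaches every droplet, and COL1A1 in ONFH neutrophils was at 1.56 and 0.756 of its T cell level, but SLC35F1 in neutrophils was at most 0.204 of its T cell level (0.0690 in ONFH replicate 2). This argues against free RNA as the whole explanation. A donor variant or a library batch would follow whole libraries, as the separation of the groups in 12 of 13 tested classes does, but a disease difference might do the same. These cannot be told apart here, because group and library coincide and the labels give neither genotypes nor batches.

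The list of glucocorticoid-induced genes was lower by camera in 8 of 13 classes in ONFH, mainly in replicate 1, with an adjusted p = 0.853 with an estimated correlation for each call. A disease difference shared by the ONFH libraries would lower both, but without ONFH replicate 1 the values of ONFH replicate 2 lay below all OA libraries in 16.9% of 65 pairs of the 5 named genes and classes, where chance gives 25%. Loss of short-lived transcripts in ONFH replicate 1 would also lower immediate early genes, which were lowest in it in 17.8% of 225 pairs, near the 18.9% of all genes. Lower glucocorticoid signalling at sampling in ONFH replicate 1 stays open: the other 14 members of the list were lowest in that library in 52.6% of 171 pairs, but they belong to the list that showed the pattern and so are no independent test. Pairs that share a gene or a class are not independent, no label gives treatment at sampling, and a disease difference seen in 1 of the ONFH libraries is not excluded.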
